A study of Mus musculus with 9 samples.

How the data were processed

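Total RNA from dissected mouse outflow tracts was isolated on RNeasy columns and made into libraries with a low-input SMART-Seq kit, per the labels' protocols. The deposited files hold whole-number read counts per gene symbol, 1 file for each of the 9 libraries, over 48397 symbols. Per the submitters' processing notes, STAR 2.5.0c, Picard, HTSeq 0.6.0, DESeq2 and the mm10 build were used; their order, the gene annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, genes that overlap an annotated partner on the opposite strand (among them Fgf10, Krt8, Des, Bnc1, Rspo3, Opn4, Nppa, Gata6, Hand2, Ankrd37, Rgs8, Dchs2, Ckm, Eln and Has2) can hold reads of that partner. The 5 rows of the deposited counts that name no gene held 20.6% to 23.5% of reads per library, mostly reads with several alignments, and were left out of library sizes and tests. The 10 most abundant genes took 3.46% to 5.00% of counts. Of the symbols, 46394 matched the GENCODE annotation of mm10, as did 16011 of the 16522 tested; coordinates come from that annotation.

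The deletion libraries and the wild-type libraries were grouped by their sample titles. A litter for each library was read from a number in the name of its deposited count file, not from the sample labels. That this number stands for a litter is an assumption throughout. The number of deletion 5 occurs once and can be a transposition of that of the second litter. It was therefore treated both as its own level and as that litter. As its own level, and in the block by replicate number, deletion 5 stands alone and adds nothing to the genotype estimate. The labels number the samples of a group without saying that each is 1 embryo, so p-values measure only the spread between these samples, which may be partly technical.

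Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersion, TMM factors, low counts filtered by filterByExpr with a minimum count of 10 in the smallest group of 4 libraries, genotype as the only term, two-sided, Benjamini-Hochberg adjusted p of 0.05). Log2 fold changes are deletion against wild type. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 with voom and sample quality weights were run as alternatives, the former with its own size factors and independent filtering. Fold changes of the genes called by DESeq2 are given from DESeq2, and all others from edgeR. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 33 lists. Nkx2-5 was also tested by enumerating all labellings of its log2 CPM values.

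The main tests, the gene lists, the rule for the genes named and most alternatives were set before the data were examined. The rule took Nkx2-5, up to 12 edgeR calls per direction, up to 4 called members per list or, for a list past camera without one, its 2 members with the smallest p, genes within 1 Mb of Nkx2-5 that passed over that window, and 11 genes of outflow tract development given whatever their p (Isl1, Fgf10, Tbx1, Gata6, Mef2c, Hand2, Nppa, Sema3c, Plxna2, Acta2 and Myh11). Since edgeR called no gene, the genes called by DESeq2 and the genes singled out in particular libraries or litters, Rspo3 included, were chosen after their values were seen. The lists cover heart muscle, smooth muscle, epicardium, endothelium, cushion, neural crest, neural, blood, foregut and skeletal muscle cells, signalling pathways, Hox and conotruncal defect genes, cell cycle, p53 targets, hypoxia, respiratory chain and stress genes; sex-linked genes were kept out of the list tests.

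Replicate numbers are shared between genotypes. Deviations of same-numbered libraries from their group means correlated at 0.242, 0.137, 0.227 and 0.176 for numbers 1 to 4, so the numbers were taken to pair the samples, and fits with the number as a block are given where they changed a call. The numbers 1 and 2 fall in the first litter and 3 and 4 in the second, and the best partner was not the same-numbered library for wild type 2 (deletion 1), wild type 4 (deletion 3) and deletion 2 (wild type 1). Across genotypes the mean correlation of deviations was 0.192 within a litter and -0.190 between litters. The values thus do not show a pairing by number beyond that of litter.

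Alternatives covered other normalizations, filters and tests, the replicate block, litter, Y-linked expression and a surrogate variable (sva 3.50.0) as covariates, removal of erythroid genes, fits within litters and leaving out each library. The procedure was tested on simulated counts for the 16522 genes with 4 and 5 libraries. Genes were drawn independently and without litter differences. Of 50 genes changed at each size, edgeR recovered 14% at 1.5-fold, 54% at 2-fold, 74% at 4-fold and 82% at 8-fold, with 9 false among 121 calls. DESeq2 recovered 24%, 68%, 86% and 94%, with 36 false among 172 calls. In these simulated counts edgeR thus often missed differences of 2-fold or less at this number of libraries. It also missed some of 4-fold and 8-fold. Some genes that entered these fits and counts are not reported here.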

Results

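Gene expression was measured by RNA sequencing in cardiac outflow tracts dissected from C57BL/6J mouse embryos at embryonic day 12.5. The outflow tract is the arterial pole of the heart, built largely from second heart field progenitors and neural crest cells. There were 4 libraries of wild-type samples and 5 of littermates homozygous for a deletion of the enhancer through which the cardiac transcription factor gene Nkx2-5 is driven in the anterior second heart field. Between 27707400 and 49094200 reads were assigned to genes per library, and between 20606 and 22093 genes had at least 1 count. No pair of libraries agreed within sampling noise, so all 9 were kept as separate samples. The numbers carried by the deposited libraries were read as litters, which is an assumption. They placed wild types 1 and 2 with deletions 1 and 2 in the first litter. Wild types 3 and 4 fell with deletions 3 and 4 in the second. Deletion 5 carried a different number. Y-linked genes exceeded 10 CPM (counts scaled to a common library total) in 3 of the 4 wild-type and 3 of the 5 deletion libraries.

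Nkx2-5 itself was lower in the deletion libraries. Its mean was 36.3 ± 11.9 CPM (SD, n = 4) in wild type and 17.5 ± 4.64 CPM (SD, n = 5) in the deletion, a log2 fold change of -1.05 (SE 0.26). Transcript remained in every deletion library, between 11.4 and 24.4 CPM. Wild type 1 stood at 18.8 CPM, inside the range of the deletion libraries, and the other 3 wild types at 39.5 CPM or more. An exact two-sided permutation test over all 126 labellings of the log2 CPM values gave p = 0.0238. Permuting only within litters, with deletion 5 read as a member of the second litter, gave an exact p of 0.0333, where 0.0167 was the smallest p possible. The log2 fold change was -0.55 within the first litter and -1.53 within the second, and the test of that difference between litters gave an interaction of -0.96 (SE 0.54) with an edgeR adjusted p of 0.718. The edgeR p of Nkx2-5, a gene set in advance, was 0.00225 unadjusted and 0.896 when adjusted over all 16522 genes tested. DESeq2 gave an adjusted p of 0.0544 over all libraries, and 0.0495 without its outlier filter (Cook's distance). With the replicate number as a block it was 0.0241. With litter as a factor it was 0.0596, or 0.0231 with deletion 5 read as the second litter. Deletion 5 is alone at its level in the block fit and the 0.0596 fit, so it adds nothing to their genotype estimates. When each library was left out in turn, the DESeq2 adjusted p passed 0.05 only without wild type 1 (4.01e-05) and without deletion 2 (0.00403). It was otherwise between 0.119 and 0.363. Within the first litter alone it was 0.854, and within the second with deletion 5 it was 1.32e-08. Nkx2-5 occupies chromosome 17 from 26838664 to 26845009 on the minus strand of mm10 and is protein coding.

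**Figure D1:**
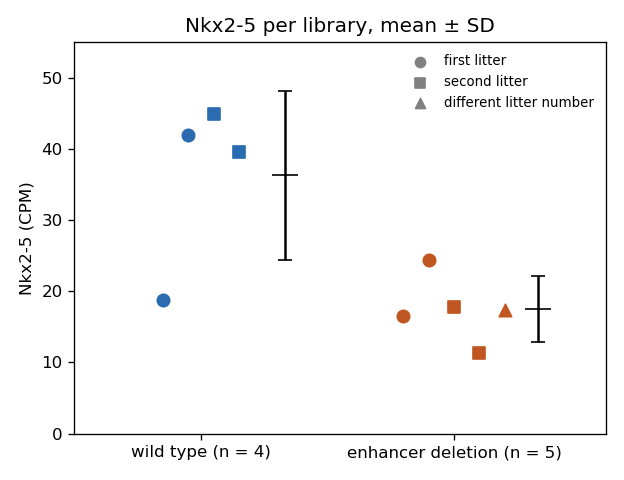
Nkx2-5 in CPM for each library, with wild type on the left and the enhancer deletion on the right; marker shape gives the litter, and the bars are the mean and SD. The 5 deletion libraries lie at or below 24.4 CPM and 3 of the 4 wild types lie above 39, with wild type 1 at 18.8 CPM.

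Nkx2-5 was also set against heart muscle transcripts as a group, a comparison chosen after the results were seen. The mean log2 CPM of the sarcomere genes was lower by 0.18 in the deletion libraries (log2 difference -0.18, exact two-sided permutation p = 0.429). Relative to that mean, Nkx2-5 was lower in all 5 deletion libraries than in all 4 wild types, with a log2 difference of -0.84. The exact two-sided permutation p of 0.00794 was the smallest that 126 labellings allow. Wild type 1, whose Nkx2-5 lay inside the range of the deletion libraries, had the lowest sarcomere mean of any library, at 7.23 log2 CPM.

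The next comparison asked which other genes differed between deletion and wild-type outflow tracts. Among second heart field progenitor genes, Fgf10, a growth factor of these progenitors, was higher in the deletion, at 12.1 ± 1.95 CPM (SD, n = 5) against 5.97 ± 2.34 (SD, n = 4), a log2 fold change of 1.01 (SE 0.26). Sema3c, a semaphorin of the outflow tract myocardium that guides cardiac neural crest cells, was lower, at 139 ± 31.2 CPM against 242 ± 59.5, a log2 fold change of -0.81 (SE 0.20). These were the 2 of the 29 tested progenitor genes that passed edgeR when adjusted over the list alone. Rspo3, an enhancer of Wnt signalling, and Sema3c passed in the same way among the 13 outflow tract myocardium markers, with Rspo3 at a log2 fold change of -0.72 (SE 0.17). All 3 had deletion and wild-type values that did not overlap. These 3 genes passed in the same libraries, so the lack of overlap adds no support. Their edgeR adjusted p over all genes was 0.896 for Fgf10 and Sema3c and 0.815 for Rspo3.

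The remaining second heart field, neural crest and smooth muscle genes chosen in advance were given as values. Isl1, a transcription factor of cardiac progenitors, had a log2 fold change of 0.84 (SE 0.36), with 142 CPM in deletion 2 and at most 59.7 CPM in any other library, and 0.38 without deletion 2. Tbx1, a second heart field regulator, was at -0.98 (SE 0.40), from -1.41 in the first litter to 0.02 in the second. Gata6 (-0.01), Mef2c (-0.04), Hand2 (-0.16) and the neural crest receptor gene Plxna2 (0.12) differed by less than their standard errors. Nppa, the natriuretic peptide gene of chamber myocardium, was near the floor, at 0.962 CPM in wild type and 1.77 CPM in the deletion, where deletion 2 alone held 7.71 CPM. The smooth muscle genes Acta2 (-0.36, SE 0.15) and Myh11 (-1.45, SE 0.59) had edgeR adjusted p of 0.896, and Myh11 rested on wild type 1, at 34.5 CPM against at most 7.87 in the other 8 libraries.

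Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16522 genes at 0.05. At an unadjusted p under 0.05 there were 870, of which 384 were higher and 486 lower. DESeq2, the tool named in the submitters' notes, called 40 genes, 11 higher and 29 lower, and limma-voom with sample weights called 4, all lower: Pcsk6, Krt8, Clu and Gja3. With the replicate number as a block, DESeq2 called 69 genes, of which 22 were among the 40. In counts simulated for this comparison over 16522 genes, 36 of 172 DESeq2 calls and 9 of 121 edgeR calls were false. Genes were drawn independently there, with planted changes and no litter differences, so these shares cannot be carried over to the real calls. The groups did not overlap in 298 genes, or 1.80% of those tested. Chance alone gives 1.59% if all labellings of the libraries are equally likely, which leaves out the litters.

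The genes called by DESeq2 were chosen after their values were seen, since the rule fixed in advance took genes from the edgeR calls. Of the 40, 37 were also tested by edgeR, and in 36 of these the deletion and wild-type libraries did not overlap. DESeq2 picked these genes for differing between the same libraries, so the lack of overlap adds no support. The 18 genes called in every one of the 9 fits that left out a library included Pcsk6, Krt8, Pax6, Clu, Gja3, Lamb3, Itga3, Sln and Tnnt1. DESeq2 called fewer genes without wild type 2 (26) and more without deletion 2 (66) or deletion 4 (62).

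The genes called lower by DESeq2 included keratin, laminin and integrin genes. Krt8, a keratin of simple epithelia and early myocardium, stood at 14.9 ± 2.505 CPM (SD, n = 5) in the deletion and 29.7 ± 3.84 (SD, n = 4) in wild type, a log2 fold change of -0.99 (DESeq2 adjusted p = 5.27e-06). Krt19 was at -0.84, and was called in 5 of the 9 fits that left out a library. With edgeR Krt19 was at -1.42 within the first litter and -0.46 within the second. The keratin gene Krt18 was not called, at -0.41 (DESeq2 adjusted p = 0.695) with groups that overlapped. The laminin chain genes Lamb3 (-1.84) and Lamb2 (-0.38) and the integrin genes Itga3 (-0.59) and Itgb3 (-0.49) were lower as well; Itgb3 was called in 1 and Lamb2 in 0 of the 9 fits that left out a library, and neither with the replicate block. Pcsk6, a proprotein convertase that processes TGF-beta family ligands, had the smallest p, with 7.42 ± 0.836 CPM in the deletion against 19.3 ± 4.09 in wild type (log2 fold change -1.37, DESeq2 adjusted p = 2.42e-10). Clu, which encodes the extracellular chaperone clusterin, was at -0.77, and Gja3, a connexin gene, at -1.27. The muscle genes Sln, an inhibitor of the sarcoplasmic calcium pump, and Tnnt1, the slow skeletal troponin T gene, were at -1.44 and -1.15.

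Fewer genes were called higher by DESeq2. Without its outlier filter (Cook's distance) the calls were 27 higher and 31 lower. With at least 50 counts in 4 libraries required they were 5 and 24. Pax6, a transcription factor best known from eye and neural development, stood at 5.83 ± 1.66 CPM (SD, n = 5) in the deletion and 1.57 ± 0.351 (SD, n = 4) in wild type, a log2 fold change of 1.90 (DESeq2 adjusted p = 4.44e-07). Arhgap36 was at 1.33 and Opn4 at 1.17. Stfa1, Atp2b3 and BC100530 had counts too low for the edgeR filter. With the replicate block Opn4 and these 3 genes were not called.

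**Figure D2:**
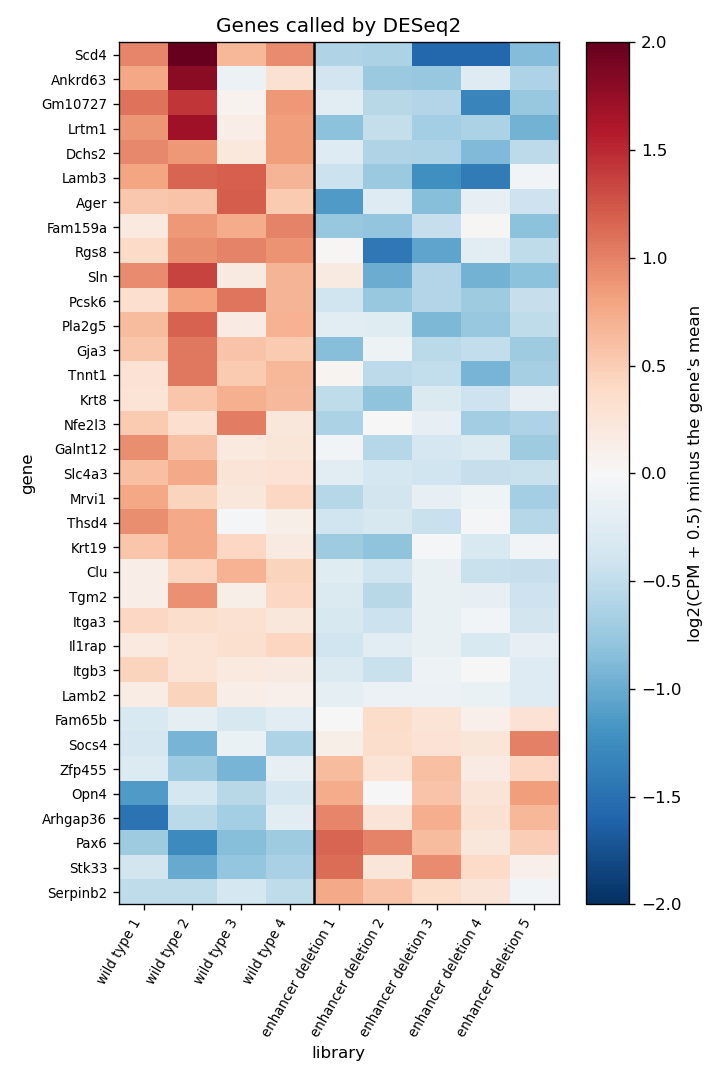
Heat map of 35 genes called by DESeq2 and tested by edgeR, one row per gene and one column per library, with the log2 CPM minus the gene's mean over the 9 libraries in colour; values beyond 2 in either direction take the end colour. Columns left of the line are wild type and those to its right are the enhancer deletion; 27 of these genes are lower and 8 higher in the deletion.

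**Figure D3:**
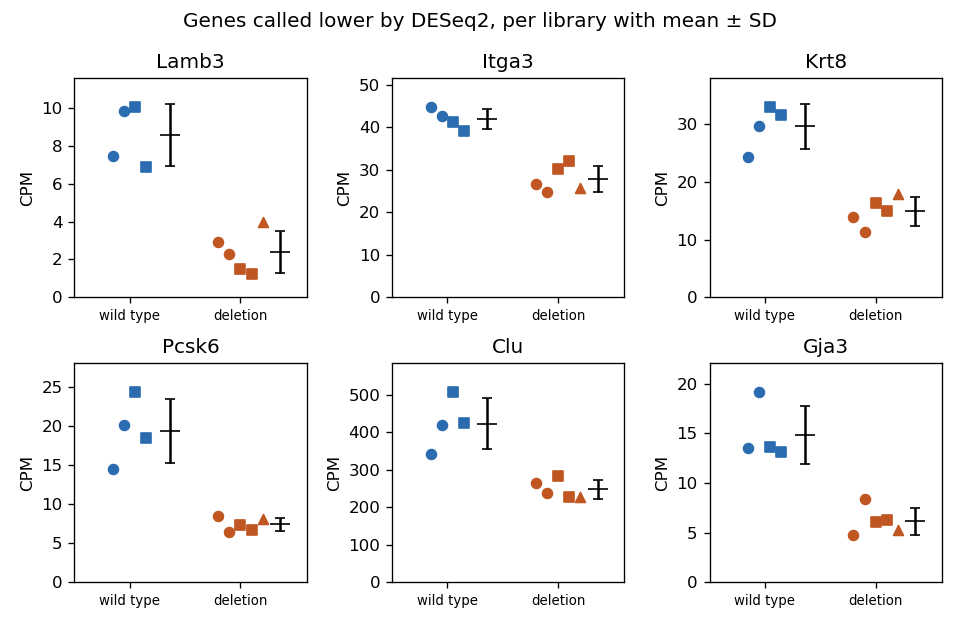
CPM of 6 genes called lower by DESeq2 for each library, with circles for the first litter, squares for the second and a triangle for deletion 5; bars give mean and SD of 4 wild-type and 5 deletion libraries. Krt8 and Pcsk6 lie at 14.9 and 7.42 CPM on average in the deletion against 29.7 and 19.3 CPM in wild type.

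Cell type and pathway lists fixed in advance were tested as groups. Of 33 lists, 6 passed camera with a preset correlation of 0.01, while 0 passed with an estimated correlation (adjusted p = 0.787 for each of the 6) and 0 passed the rotation test fry. Of those past camera at the preset correlation, epicardium markers were lower in the deletion with a median log2 fold change of -0.52 and 18 of 20 members below 0 (camera adjusted p = 4.14e-05), among them Krt19 (-0.84) and Bnc1 (-0.56). Smooth muscle markers were lower, with a median of -0.28 and 21 of 25 below 0 (camera adjusted p = 9.86e-05), among them Myl9 (-0.28) and Lmod1 (-1.27), which was at -1.98 within the first litter and -0.09 within the second. Sarcomere genes were lower by a median of -0.18 with 33 of 36 below 0 (camera adjusted p = 0.0115), among them Des (-0.36) and Alpk3 (-0.39). FGF signalling genes were higher, with a median of 0.20 and 16 of 23 above 0 (camera adjusted p = 0.0455), including the feedback phosphatase gene Dusp6 (0.52) beside Fgf10. Hypoxia and glycolysis genes were higher by a median of 0.11 with 20 of 25 above 0 (camera adjusted p = 0.0252), among them P4ha1 (0.37) and Ankrd37 (0.47). Of these 5 lists, the only member past edgeR when adjusted over the list alone was Krt19, and none passed over all genes.

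The sixth list past camera was that of neuron and Schwann cell markers. With the replicate block 8 lists passed. The endothelial (camera adjusted p = 0.0121), cardiac neural crest (0.0314) and respiratory chain (0.0492) lists were added, and the hypoxia list was no longer among them (0.276). Without wild type 2 the sarcomere median was 0.01 (adjusted p = 0.794), and without wild type 1 the hypoxia median was -0.01 (adjusted p = 0.974). The epicardium and smooth muscle medians were -0.76 and -0.63 within the first litter and -0.07 and -0.06 within the second with deletion 5.

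**Figure D4:**
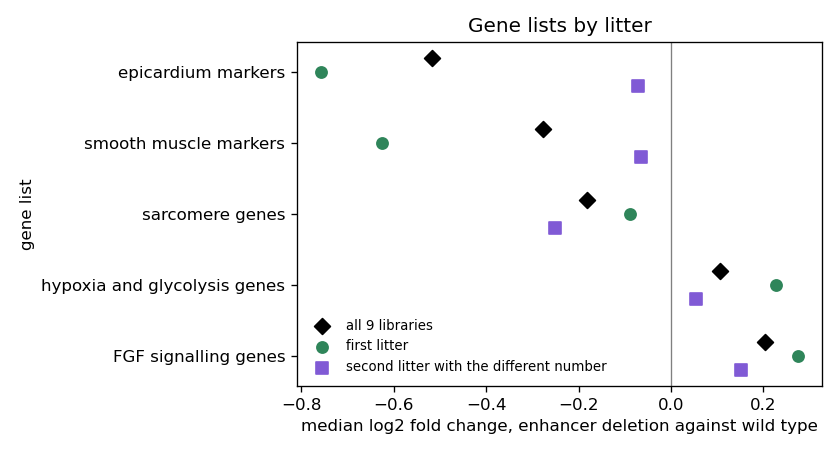
Median log2 fold change, enhancer deletion against wild type, of 5 gene lists over all 9 libraries (diamonds), within the first litter (circles) and within the second litter with deletion 5 (squares). Epicardium and smooth muscle markers lie at -0.76 and -0.63 in the first litter and at -0.07 and -0.06 in the second.

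Neuron and Schwann cell markers had a median log2 fold change of 2.31 (camera adjusted p = 0.0252, and adjusted p = 0.787 with an estimated correlation), with Th at 3.26 (SE 1.11) and Fabp7 at 4.71 (SE 2.00). Most of the shift of the list came from deletion 2. Without that library the median was -0.30 (camera adjusted p = 0.780) and Fabp7 was at -0.30, while Th was at 1.42 (SE 0.53, edgeR adjusted p = 0.905). Within the second litter, which does not hold deletion 2, the median was 0.65 over the members tested with all libraries, 0.37 with the low-count filter applied within that litter (camera adjusted p = 0.00525), and Th was at 1.56 (edgeR adjusted p = 0.191). In deletion 2, 230 genes exceeded every other library more than 4-fold, where no other library had more than 3 such genes. The neurofilament genes Nefl and Nefm stood there at 1050 and 611 CPM and at no more than 42.6 and 11.7 CPM elsewhere.

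The other lists did not pass camera over all 9 libraries with genotype as the only term. Some fits to fewer libraries passed more lists, as counted further below. Krt8 among foregut and lung epithelium markers and Sln among the atrial, ion channel and Nkx2-5-dependent lists passed edgeR when adjusted over the list alone. The list of genes described as depending on Nkx2-5 had a median of -0.04, with 9 of 21 members above 0. Its median was 0.21 within the first litter, -0.40 within the second and -0.20 without deletion 2. The small median over all libraries thus joins opposite signs in the litters. With 2 libraries per genotype in each litter, whether the list moved in the second stays open. Over all 9 libraries, the camera adjusted p of the lists that did not pass was 0.114 or more. Among heart lineages the medians were 0.04 for ventricular markers, -0.01 for atrial markers, -0.14 for ion channel and calcium handling genes, -0.11 for outflow tract myocardium markers, 0.07 for second heart field progenitor genes and -0.04 for cardiac transcription factors. Ventricular markers were at 0.20 within the first litter, -0.31 within the second and -0.18 without deletion 2. Cushion mesenchyme genes (0.31), endothelial markers (0.10), cardiac neural crest genes (0.12) and conotruncal defect genes (-0.01) did not pass either. Markers of other tissues had medians of -0.42 for macrophages and leukocytes, -0.10 for foregut and lung epithelium and -0.16 for skeletal muscle. Erythroid markers had a median of -0.0018 and a mean of -0.29. Their median was -1.32 within the first litter and 1.04 within the second. Among signalling genes the medians were -0.06 for Notch, 0.07 for BMP and TGF-beta, 0.01 for Wnt, -0.09 for retinoic acid, -0.12 for Hedgehog and -0.09 for semaphorins and plexins. Hox genes (-0.34), p53 targets (-0.04), respiratory chain genes (-0.08), immediate early and heat shock genes (0.12), S phase genes (-0.07) and G2 and M phase genes (0.02) completed the lists. Median and mean differed in sign for the Nkx2-5-dependent, Hedgehog, foregut, Wnt and G2 and M phase lists, and the erythroid and Wnt tests pointed against their medians.

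The first principal component, with 30.5% of the variance, separated litters, not genotypes. Between the first litter and the remaining libraries 1625 genes passed edgeR, 883 higher and 742 lower outside the first litter. Deletion 2 lay apart on the second component.

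**Figure D5:**
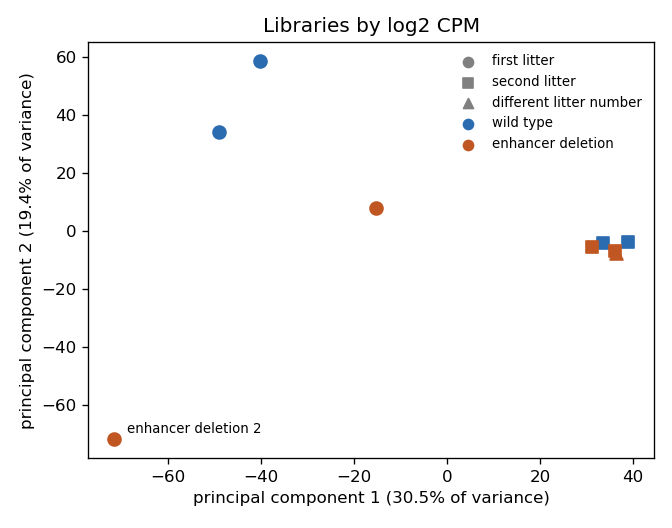
Principal components of log2 CPM, component 1 with 30.5% of the variance on the horizontal axis and component 2 with 19.4% on the vertical; blue is wild type, orange the enhancer deletion, and marker shape the litter. The libraries of the second litter and deletion 5 sit together, and deletion 2 sits apart from the others of the first litter.

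Genes around Nkx2-5 were compared because an enhancer can act on its neighbours and a targeted allele can carry linked variants. Among the other 44 genes tested within 1 Mb of Nkx2-5, the median log2 fold change was -0.01, the range was from -0.71 to 0.65, and 0 had an unadjusted edgeR p under 0.05. Nkx2-5 had an adjusted p of 0.101 over this window with edgeR and of 0.00579 with DESeq2. Within 10 Mb, where edgeR called 0 genes as it did elsewhere, 11 of 353 had an unadjusted p under 0.05, against 825 of the 15657 genes elsewhere (Fisher's exact two-sided p = 0.0885). DESeq2 called 1 of 353, Ager, which was not called with the replicate block, against 34 elsewhere (Fisher's exact two-sided p = 0.542).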

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

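The counts over all 100 drawn splits of the libraries were planned. All other tests in this part, subsets of the splits included, were chosen after the results were seen. For named genes, for depth and for the scores of the 6 lists past camera, the most extreme library of each genotype was set against the others by Dixon's ratio of gap to range. Of 150 such sets, 14 stood out, where chance gives about 1 in 20, or 7.5.

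Deletion 2 stood apart from the other deletion libraries in the neuron and Schwann cell score (ratio 0.845), in Fabp7 (0.724) and in Isl1 (0.724). The median of the 23 tested neuron and Schwann cell markers was 4.09 (log2) above the mean of the other 4 deletion libraries, with 21 of 23 higher, and 18 exceeded every other library. Nefl, Nefm and Prph stood at 1050, 611 and 331.9 CPM, and the sensory neuron genes Avil and P2rx3 stood at 87.0 and 55.6 CPM against less than 1 elsewhere; 14 of the 23 exceeded 1 CPM on average in the other 8 libraries, and 2 of the 25 listed genes belong to another list too. Neither depth nor an effect shared by the deletion libraries accounts for its size: deletion 4, with fewer counts, had a median correlation with the other libraries higher by 0.0296, and against the wild types of the same litter the median of these 23 markers, from differences of mean log2 CPM, was 4.34 (log2) in deletion 2, but -0.48 in deletion 1 and 0.58 (SD of the members 1.03) in the second litter with deletion 5. The bound for a shared effect, below the median of deletion 2 by more than the SD of the members in both litters, replaced a bound of 0.5 after these medians had been seen, and by the earlier bound the second litter leaves it undecided. A smaller shared rise in the second litter stays open. A piece of sensory ganglion or nerve in the dissected sample is consistent with these values, and remains a hypothesis.

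Wild type 1 was the lowest wild type in Nkx2-5 (ratio 0.852), Alpk3 (0.908) and Rgs8 (0.85). The lower Nkx2-5 of the deletion libraries was weighed against muscle content and litter. A smaller share of heart muscle as a whole is argued against by Nkx2-5 relative to the sarcomere genes. It was lower by a log2 difference of -0.84 with no overlap between genotypes (exact permutation p = 0.00794). The sarcomere mean does not address a smaller share of outflow tract myocardium alone, which stays open. A difference between litters as the whole cause is argued against by the log2 fold change within the second litter, -1.53 (SE 0.20); within the first it was -0.55 (SE 0.42). Reduced expression from the allele without the enhancer, the effect the design names, stays open as a hypothesis. The edgeR p of Nkx2-5 was 0.00225 unadjusted, and adjusted over all genes it did not pass 0.05.

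Smooth muscle markers were lower in the deletion by a median of -0.28. Neural content of deletion 2 is argued against, since the median without that library was -0.24. A difference in the first litter is consistent with the medians of -0.63 there and -0.064 in the second litter with deletion 5. Whether a genotype effect is present in the first litter only, or its wild types 1 and 2 differ for other reasons, cannot be told apart with 2 libraries per genotype.

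Wild type 2 was the highest wild type in Gja3 (ratio 0.896), Scd4 (0.833) and Lamb2 (0.869). Wild type 3 was the lowest in Dchs2 (0.848) and the highest in Ager (0.935) and Serpinb2 (1), a gene with no counts in the other 3 wild types. Deletion 5 was the highest deletion library in Socs4 (0.726) and deletion 1 in Wt1 (0.766).

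Chance could not be excluded for the counts over all genes. Of 100 splits of the 9 libraries into 4 and 5, the real one included, 34 gave at least the 870 genes with an unadjusted edgeR p under 0.05 (highest other 3771), 20 gave at least the 40 genes called by DESeq2 (highest other 2175), and 78 gave at least 6 lists past camera (highest other 20). The splits with the most genes follow the litters, a structure of the samples: setting the first litter against the rest gave 2838 genes with DESeq2. Among the 13 drawn splits that part all 4 numbered pairs, which keep the litters balanced, only the real one reached the 870 genes (highest other 775) and the 40 DESeq2 calls (highest other 10), while 9 reached 6 lists. Among the 47 drawn splits with 2 first-litter libraries in the group of 4, 5 reached 870 genes and 2 reached 40 calls, the other with 48.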

How the results depend on the processing

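The fits within litters, the list tests with deletion 5 read as the second litter, the other fits behind the 40 DESeq2 calls and DESeq2 over the 1 Mb window were chosen after seeing the data; all other alternatives were planned. Nkx2-5 was lower in every setting, with an edgeR log2 fold change between -0.93 and -1.27 when each library was left out in turn, and its edgeR adjusted p did not pass 0.05 in any. Genes changed numbered 40 with DESeq2, 4 with limma-voom, 6 within the second litter (Casq2, Cox6a2, Col2a1 and Perp lower, Hsd3b6 and Sparcl1 higher), and from 0 to 1 when each library was left out, the 1 being the predicted gene Gm3375 without wild type 3; all other settings, the replicate block included, gave 0. The cause was not tested. DESeq2 called 69 genes with the replicate block, 100 with litter as a factor, 122 with deletion 5 read as the second litter (39 of the 40 among them), 282 within the first litter, 93 within the second with deletion 5, and from 26 to 66 with each library left out. Some of the 122, such as Neurod1 and Pou4f3, have reads in deletion 2 alone. Near Nkx2-5 the count was 1 with DESeq2 in either window. Within 1 Mb, adjusted over that window, it was Nkx2-5 itself, and within 10 Mb, adjusted over all genes, it was Ager.

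Lists past camera numbered 0 with an estimated correlation, 0 with fry in its directional and 0 in its mixed form, 10 within the second litter, 13 within the second litter with deletion 5, and from 4 to 11 with each library left out, the highest without deletion 1. The block added the endothelial, neural crest and respiratory chain lists and lost the hypoxia list.

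Values near 0 or resting on few libraries changed sign, and the cause was not tested except where deletion 2 alone decides them. Gata6 was 0.013 with voom, 0.0018 with the block, 0.0025 with litter, 0.0026 with the surrogate variable, 0.15 within the second litter, 0.065 with deletion 5 added, and from -0.077 to 0.046 with each library left out. Nppa was -1.16 with voom, -0.18 with the block, -0.14 with deletion 5 read as the second litter, -1.12 with the surrogate variable, -1.35 within the second litter, -1.79 with deletion 5, and from -1.69 to 1.19 with each library left out. Leaving out each library gave Fabp7 from -0.30 to 5.04 and the neuron and Schwann cell list from -0.30 to 2.65, both lowest without deletion 2, Mef2c from -0.12 to 0.019 and Plxna2 from -0.043 to 0.22. Within the second litter Fabp7 was -0.79 (-0.35 with deletion 5), Tbx1 0.024, Eln 0.11 and the hypoxia list -0.050. Within the first litter Mef2c was 0.033 and Hand2 0.062.

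The libraries held 27707400 counts or more, and no pair of libraries agreed within counting error. Counts thinned to a lower depth were not tried, so whether depth limits the calls among genes with low counts was not tested.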

Other observations

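The tests and genes of this part were chosen after the results were seen. With edgeR more genes differed between the first litter and the remaining libraries (1625) than between the genotypes (0). The lists were not tested for this comparison, and their medians are given as values. Macrophage and leukocyte markers were lower outside the first litter by a median log2 difference of -1.38 and Hox genes by -0.84. Neuron and Schwann cell markers were at -2.50, and at -0.94 without deletion 2. S phase and G2 and M phase genes were higher by 0.38 and 0.44 and outflow tract myocardium markers by 0.51. Among single genes, Igf2bp1, an RNA-binding protein gene of fetal growth, was at 1.33, the mitotic kinase gene Plk1 at 0.77, the macrophage genes Lyz2 and F13a1 at -2.63 and -2.24, and the caveolin gene Cav1 at -1.87, each with an edgeR adjusted p of 0.00265. A separate fit without deletion 2 gave 1401 genes, whose overlap with the 1625 was not counted. The labels give all embryos the same stage. Y-linked genes exceeded 10 CPM in every first-litter library but not in wild type 4, deletion 4 and deletion 5. Stage, sex and dissection were not tested as explanations.

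With litter as a factor and deletion 5 read as the second litter, DESeq2 called further genes in the deletion. Casq2, the calcium store protein of the sarcoplasmic reticulum, was at -1.10 and Ckm, the muscle creatine kinase gene, at -1.59. Sema3c (-0.83), the semaphorin co-receptor gene Nrp2 (-0.63), Rspo3 (-0.71), Lama5 (-0.78) and Nkx2-5 (-1.05, adjusted p = 0.0231, against 0.0596 with deletion 5 as its own level) were lower, and Fgf10 (1.09), the Wnt antagonist gene Dkk1 (1.38) and the hyaluronan synthase gene Has2 (0.96) were higher. With edgeR Has2 was at 1.79 within the first litter and 0.18 within the second. The genotype effect differed between litters, by edgeR's interaction test over the 8 libraries of the shared litters, for 2 genes, the adult globin genes Hbb-bs (3.52) and Hbb-bt (3.42), near-identical copies whose reads can be split between them (adjusted p = 0.0350 for each).

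A hypothesis from the laminin genes called by DESeq2 is that basement membrane genes are lower as a group. A set of 29 laminin, nidogen, collagen IV, integrin and related genes was written down after 9 of them, Lama5, Col4a6, Frem2 and Bcam included, had been seen among the DESeq2 calls without or with litter, so these 9 were left out of the test. Among the other 20, 17 had a log2 fold change below 0, with a median of -0.19, and Itga6 (0.34), Col18a1 and Lama4 lay above 0. The medians were -0.26 within the first litter and -0.13 within the second with deletion 5. The directional p of fry was 0.0782 and that of camera with the preset correlation 0.00126, so whether basement membrane genes are lower as a group stays open.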
